A study of Mus musculus with 10 samples.

How the data were processed

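RNA of mouse kidneys was measured on 10 one-colour Affymetrix arrays, each hybridised with biotin-labelled RNA of one kidney group and one preparation. The kidneys came from untreated mice or were the unclamped, contralateral kidneys of mice whose other kidney had been clamped. Per the labels' protocols, RNA was isolated on columns, its quality was measured on a Bioanalyzer, and it was labelled by a T7-based strategy. The protocols also describe linear amplification. The titles name 3 preparations: total RNA, amplified total RNA and newly transcribed RNA, the last being RNA that carries 4-thiouridine (s4U) given to the living mouse.

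The authors deposited 1 signal intensity per probe set and array, on a linear scale. The summary algorithm, any scaling and any detection calls are not given in the sources used here, so no probe set is described as above or below background. The median deposited intensity ran from 18.6 to 70.3 between arrays, so the arrays had not been put on one scale. Values were transformed as log2(intensity + 11.8), where 11.8 is the 25th percentile of all values, and then quantile normalized. A log2 difference on this scale understates the change of dim genes. Of 22690 probe sets, 64 control probe sets were set aside, and those whose mean over the 10 arrays lay above the 40th percentile were tested, which left 13575.

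Gene symbols came from the platform annotation, which lists 21071 probe sets. Of these, 20380 have 1 symbol and 691 have several, and 1555 probe sets are not listed and are unnamed here. Symbols were checked by Entrez number against a RefSeq table (assembly GRCm38.p6, used for names only), and 0 changed. The tested probe sets with 1 symbol numbered 12502 and covered 8300 genes. A gene is represented by its probe set with the highest mean over all arrays, and other probe sets of a named gene are mentioned where they disagree.

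All tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every fit used all 10 arrays, so that the groups share one estimate of the spread. The contralateral effect over all preparations and the 2 comparisons between preparations came from an additive model of kidney and preparation, with 6 residual degrees of freedom. The contralateral effects within a preparation, and the differences between those effects, came from a model with 6 group means and 4 residual degrees of freedom. The newly transcribed RNA has 1 array per kidney group: its lone arrays are assumed to vary like the other groups, and its difference has no replicate check. A ± value after a log2 difference is limma's standard error.

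The 29 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 232 tests of 29 lists in 8 comparisons, and again with the correlation estimated for each list. With the preset value 54 of the 232 tests passed. With an estimated correlation 4 did: glucocorticoid-responsive genes over all preparations and in total RNA, immediate early and stress regulators over all preparations, and proteasome subunits in newly transcribed against amplified total RNA. Some genes are in several lists; 11 of the 22 measured glucocorticoid-responsive genes are also in another list. For the newly transcribed arrays, each list's median was also ranked among 10000 random lists of the same size matched on mean signal. Each list's median and its test pointed the same way wherever the test passed.

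Named genes followed a rule. Per comparison these were the 8 largest rises and 8 largest falls among probe sets that passed, had 1 symbol and did not overlap between groups within any preparation with 2 arrays per group. Where fewer than 8 passed, the smallest unadjusted p filled the rest, said not to have passed. From each list that passed or had members past the threshold, up to 3 members with the largest change were added, of which the text gives a part. A gene named in one comparison may be given its value in others.

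The titles call the arrays of a group biological replicates. They do not say whether arrays of the same number in different preparations come from the same mouse, and p-values then measure the spread between these arrays only. The number of arrays limits the precision. The fits were tested on simulated log2 values, with noise drawn from the real arrays' spread within groups. The transformation, normalization and filter were not simulated. Of 13575 probe sets, 100 were changed by a log2 difference of 1 and another 100 by 2. For the additive model the simulation held no contralateral effect that differs between preparations, while the real fits carry such differences in their spread. Its recovery need not hold for the real arrays. Of the 100 with a difference of 1, the fit recovered 100% for the contralateral effect over all preparations, 93% in total RNA, 90% in amplified total RNA and 63% between the newly transcribed arrays, which were simulated to vary like the others. It recovered 96% for newly transcribed against amplified total RNA and 100% for amplified total against total RNA. For the difference of contralateral effects it recovered 36% (newly transcribed against amplified total RNA) and 50% (amplified total against total RNA). False calls, in the same order of comparisons, numbered 22, 12, 15, 13, 14, 12, 5 and 10. In each comparison except the one with 5, the false calls are a larger share of the calls than the threshold of 0.05 aims at. The 22 over all preparations are the largest share.

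The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Alternatives covered the scaling between arrays, the offset, the filter, the variance model, array weights, the replicate number as a block, the arrays in the fit and each array left out. Fits without a newly transcribed array, a fit with the Gapdh 3'/5' ratio as a covariate and the gene lists on median-scaled arrays were added after the arrays' quality was seen.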

Results

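The series profiled kidneys of male C57/BLACK6 mice, 7 weeks old and about 20 g in weight. In one group of mice the kidney of one side was clamped for 45 min and the unclamped contralateral kidney was removed 3 h after reperfusion. These mice received s4U at 200 µM 1 h and 2 h after reperfusion. Normal mice received s4U at 0 h and 1 h, and their kidneys were removed at 2 h. No sham operation is described in the labels, so surgery, anaesthesia and the time points go together with the kidney group. Per kidney group there were 2 arrays of total RNA, 2 of amplified total RNA and 1 of newly transcribed RNA. The design asks which genes change in the contralateral kidney, and how far the change is one of RNA synthesis.

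Brightness and 3' bias differed between arrays. The median deposited signal was 18.6 on the contralateral newly transcribed array and 70.3 on the normal one, and 26.6 to 59.7 on the 8 other arrays. The Gapdh control probe sets gave a 3'/5' signal ratio of 0.938 to 1.12 in total RNA, 4.21 to 6.23 in amplified total RNA, 12.7 on the normal newly transcribed array and 68.9 on the contralateral one. The Actb ratio ran from 1.30 to 1.85 in total RNA and from 7.34 to 8.29 in amplified total RNA, and was 12.7 and 24.8 on the newly transcribed arrays. Within total RNA the contralateral arrays differed from the normal ones without overlap: Gapdh ratios were 1.03 and 1.12 against 0.938 and 0.973, Actb ratios 1.70 and 1.85 against 1.30 and 1.43, and median signals 40.5 and 41.6 against 55.9 and 59.7. The first principal component, with 52.8% of the variance, followed the preparation, and the second, with 20.7%, parted the newly transcribed arrays from each other.

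**Figure D1:**
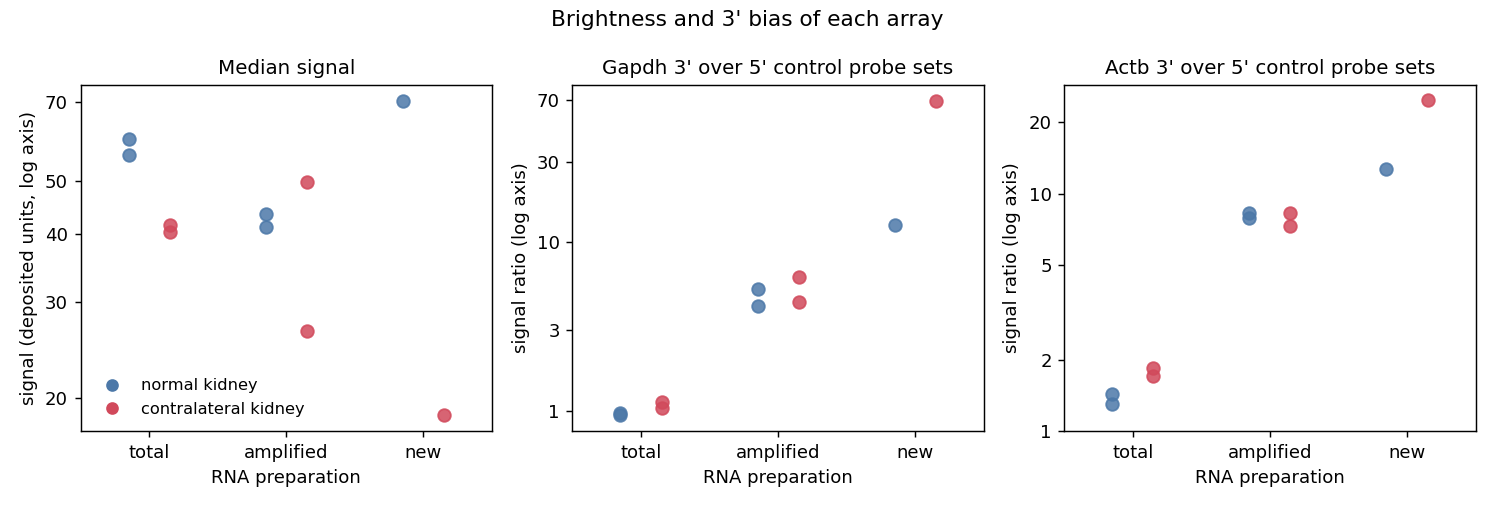
Median deposited signal and the 3' over 5' signal ratios of the Gapdh and Actb control probe sets (log axes), 1 point per array, by preparation and kidney. The contralateral newly transcribed array has the lowest median signal, 18.6, and the highest Gapdh ratio, 68.9.

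Contralateral kidneys were first compared with normal kidneys over all preparations. Among the genes named by the rule, Cebpd, a transcription factor of the acute phase response, rose by 2.43 ± 0.28 on the log2 scale (adjusted p = 0.00546) and Hmox1, which degrades heme, by 2.37 ± 0.34 (adjusted p = 0.0201). Cdkn1a, a cyclin-dependent kinase inhibitor, rose by 2.32 ± 0.17 (adjusted p = 0.000401) and Igfbp1, a binding protein of insulin-like growth factors, by 2.10 ± 0.13 (adjusted p = 0.000136). The other large rises were Socs3, a feedback inhibitor of cytokine signalling (2.16), the metallothioneins Mt1 (1.93) and Mt2 (1.68) and the neutrophil chemokine Cxcl1 (1.67). Cyp27b1, the enzyme that makes active vitamin D, fell by 1.53 ± 0.20 (adjusted p = 0.0115), the gap junction gene Gjb2 by 1.22 ± 0.13 (adjusted p = 0.00346), Timd2 by 0.95, Nepn by 0.84, Rnf183 by 0.75 and Nat8f1 by 0.68. Tcf21 (-0.78) and Paqr7 (-0.72) had the next smallest p and did not pass (adjusted p = 0.0536 for each).

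In all, 60 of 13575 probe sets passed, 52 higher and 8 lower. Of the 22 measured glucocorticoid-responsive genes 10 rose and 0 fell (15 rose when adjusted over the list alone), with a list median of 0.85. The list's adjusted p was 1.91e-15, and 0.0193 with an estimated correlation. Immediate early and stress regulators rose in 6 of 25 (17 adjusted over the list alone), among them Egr1 by 1.10, Gadd45g by 0.98 and Fos by 0.95. Over the alternative fits Egr1 kept its call in 13 of 23, Gadd45g in 14 of 23 and Fos in 11 of 22. The list's call held with an estimated correlation (adjusted p = 0.0417).

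Other lists were called higher at the preset correlation and not with an estimated one. Of the IL-6 and STAT3 acute phase genes 6 of 19 rose (14 adjusted over the list alone), Steap4 by 1.51 besides Cebpd and Socs3; adjusted p = 0.186 with an estimated correlation. Cxcl1 and Nfkbia (0.60) were the 2 of 10 NF-kB cytokine and adhesion genes that rose (7 adjusted over the list alone, adjusted p = 0.211 with an estimated correlation). Over the alternative fits Cxcl1 kept its call in 19 of 22 and Nfkbia in 10 of 23. Igfbp1 and Angptl4 (1.58), an inhibitor of lipoprotein lipase, were the 2 of 17 fasting and PPARA genes that rose (7 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). Hmox1, Mt1 and Mt2 were the 3 of 15 NRF2 and metallothionein genes that rose (4 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation).

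In 4 more lists called higher, 0 members passed over all genes. These were ribosomal proteins (median 0.25 over 46 genes; adjusted p = 0.78 with an estimated correlation), interferon-stimulated genes (0.35 over 16; adjusted p = 0.549 with an estimated correlation) and leukocyte markers (0.23 over 16; adjusted p = 0.612 with an estimated correlation), each with 0 members adjusted over the list alone. The markers of adipose, muscle and adrenal tissue, which could come with dissected kidneys, had a median of 0.70 over 5 genes, with 2 members higher adjusted over the list alone (adjusted p = 0.475 with an estimated correlation). None of these 4 lists passed in total RNA or in amplified total RNA. The medians of the ribosomal and interferon lists were 1.01 and 0.78 between the newly transcribed arrays, 1 against 1. The medians of the leukocyte and of the adipose, muscle and adrenal lists were -0.04 and 0.01 in total RNA, 0.32 and 0.41 in amplified total RNA, and 0.80 and 1.79 between the newly transcribed arrays.

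The other 19 lists did not pass, with medians from -0.28 to 0.31 and adjusted p from 0.0665 to 0.956. They cover heat shock chaperones, the unfolded protein and ATF4 response, p53 targets, hypoxia, the circadian clock, tubular injury, vasoactive and renin-angiotensin genes, cholesterol synthesis, the cell cycle and short-lived regulators. They also cover respiratory chain and proteasome subunits, red blood cell genes, fibroblast and smooth muscle markers, and markers of the proximal tubule, thick limb and distal tubule, collecting duct, podocytes and endothelium. In them Cdkn1a, named above and also a p53 target, rose. So did Sesn2 (1.53) and Psat1 (1.27), which respond to amino acid stress, and the clock regulator Nfil3 (1.21).

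The count over all preparations depended on single arrays. It was 12 without normal total RNA replicate 1, 18 without replicate 2, 21 and 18 without contralateral total RNA replicate 1 or 2, 20 and 25 without normal amplified RNA replicate 1 or 2, 19 and 26 without contralateral amplified RNA replicate 1 or 2, 332 without the normal and 318 without the contralateral newly transcribed array. Of the 8 rises and 6 falls named first, 14 genes, Cebpd, Cdkn1a, Igfbp1, Mt2 and Gjb2 passed in each of these 10 fits, and the other 9 lost the call in at least 1 of them and kept their direction. Angptl4 also passed in all 10.

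**Figure D2:**
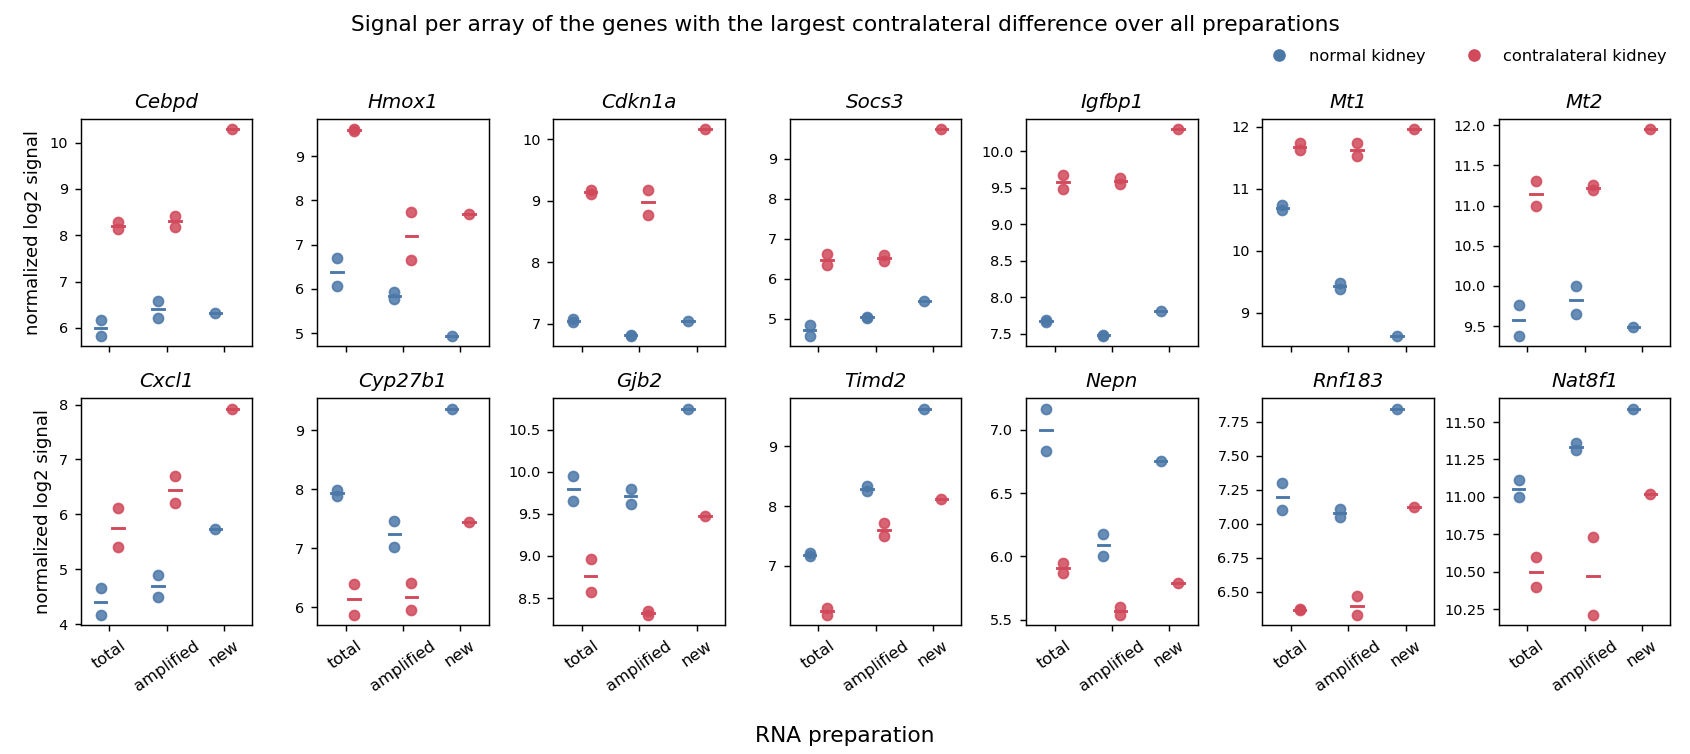
Normalized log2 signal (vertical axes) by RNA preparation for the 8 largest rises and the 6 falls over all preparations that met the rule for named genes; points are arrays and bars are group means. All 10 arrays shown were part of the fit that chose these genes.

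In total RNA, whose titles name no amplification, contralateral kidneys had 214 probe sets higher and 45 lower than normal kidneys. These arrays also differed in 3' bias and brightness by kidney group. Hmox1 rose by 3.21 ± 0.30 (adjusted p = 0.000409), from a normalized log2 signal of 6.38 ± 0.44 (SD, n = 2) in normal to 9.59 ± 0.029 (SD, n = 2) in contralateral kidneys. Pdk4, which inhibits pyruvate dehydrogenase, rose by 2.59 (adjusted p = 0.0228), Cebpd by 2.20, Cdkn1a by 2.09, the TWEAK receptor gene Tnfrsf12a by 2.05, the mitochondrial nucleotide carrier gene Slc25a33 by 2.03, the nuclear non-coding RNA Malat1 by 1.92 and Igfbp1 by 1.90. Cyp27b1 fell by 1.80 (adjusted p = 0.00205), Spsb4 by 1.63, the transcription factor gene Tcf21 by 1.14, the ribosomal protein gene Rps27 by 1.13, Nepn by 1.09, Tspyl4 by 1.08, Gjb2 by 1.03 and neuropeptide Y (Npy) by 0.98.

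Of the 22 glucocorticoid-responsive genes 15 rose in total RNA (18 adjusted over the list alone), with a list median of 1.12; the call held with an estimated correlation (adjusted p = 0.0362). Immediate early and stress regulators rose in 11 of 25 (15 adjusted over the list alone), with Gadd45a at 1.31, Dusp1 at 1.21 and Klf6 at 1.08 (adjusted p = 0.203 with an estimated correlation). Acute phase genes rose in 9 of 19 (10 adjusted over the list alone), with Socs3 at 1.77 and haptoglobin (Hp) at 1.45 (adjusted p = 0.0782 with an estimated correlation). Fasting and PPARA genes rose in 7 of 17 (10 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation). Cxcl1 was the 1 of 10 NF-kB genes that rose (3 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation). Over the alternative fits, Cxcl1 kept its call in total RNA in 5 of 17 and Hp in 4 of 17. Dusp1 kept it in 17 of 18, and Nfil3, named below, in 3 of 11.

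Smaller list shifts in total RNA passed at the preset correlation. Short-lived regulators had a median of 0.20, with 2 of 30 higher, Nfil3 (1.05) and Tgif1 (0.86), and adjusted over the list alone 6 higher and 1 lower; adjusted p = 0.29 with an estimated correlation. Tubular injury markers had a median of 0.25 with 0 of 10 past the threshold and 1 adjusted over the list alone (adjusted p = 0.23 with an estimated correlation). Of the NRF2 and metallothionein list Hmox1, Mt2 (1.58) and Mt1 (0.98) rose, 3 of 15 also when adjusted over the list alone, while its median was 0.03 (adjusted p = 0.29 with an estimated correlation). Of the p53 targets Cdkn1a, Trp53inp1 (1.12) and Sesn1 (0.80) rose, 3 of 14 (4 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation). The count of 259 was 48 without normal total RNA replicate 2 and 49 without contralateral total RNA replicate 1, and 146, 135, 132 and 131 without normal total replicate 1, contralateral total replicate 2, and normal amplified replicates 1 and 2. Of the 16 genes named first, 9 passed in all 8 such fits; Pdk4, Spsb4, Rps27, Nepn, Tspyl4, Gjb2 and Npy did not, and kept their direction.

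In amplified total RNA, 556 probe sets were higher and 844 lower in contralateral kidneys. Mt1 rose by 2.19 ± 0.099 (adjusted p = 7.5e-07), Cdkn1a by 2.15, Igfbp1 by 2.12, Cebpd by 1.90, Pdk4 by 1.86, Hp by 1.85, Slc25a33 by 1.75 and Cxcl1 by 1.74. Malat1 fell by 2.96 ± 0.19 (adjusted p = 8.43e-06) and Slc4a4, the sodium bicarbonate cotransporter gene, by 2.64 ± 0.11 (adjusted p = 7.5e-07). The other large falls were the transcription factor genes Sox6 (-2.48) and Zbtb20 (-2.34), the kinase gene Taok3 (-2.46), Evi5 (-2.29), the chloride transporter gene Clcn3 (-2.21) and the taurine transporter gene Slc6a6 (-2.03). Of the other probe sets, the 1 of Evi5 and 1 of 2 of Taok3 went the other way.

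The amplified RNA shared lists with total RNA. Glucocorticoid-responsive genes rose in 14 of 22 (16 higher and 1 lower adjusted over the list alone; adjusted p = 0.0782 with an estimated correlation) and acute phase genes in 10 of 19 (13 adjusted over the list alone; adjusted p = 0.147 with an estimated correlation). Immediate early regulators rose in 9 of 25, Fos by 1.29 (16 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation). NF-kB genes rose in 6 of 10, among them Nfkbiz (1.08) and the adhesion molecule Icam1 (0.68), with 8 adjusted over the list alone (adjusted p = 0.186 with an estimated correlation). Fasting and PPARA genes rose in 6 of 17 and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.514 with an estimated correlation). The count of 1400 was 540 and 513 without normal amplified replicate 1 or 2, and 14 of the 16 named genes passed in all 8 fits that left out an array; Pdk4 and Hp did not.

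Total and amplified total RNA share no array, so their calls could be set against each other. Their arrays may come from the same mice, so agreement between them need not be a replication in other animals. Both called 93 probe sets higher, where independent lists would share 8.76, and 15 lower, where they would share 2.80. The tests take each probe set's spread from the same fit, so their calls are not independent and may overlap more in either direction. No such number was worked out for opposite calls. A further 41 probe sets, which represent 33 named genes and 3 unnamed probe sets, were called higher in total and lower in amplified RNA, and 0 the other way; they include 3 probe sets of Malat1 and those of Atrx, Kcnj15, Ppara and Ppargc1a. Across all 13575 probe sets the contralateral differences of total and amplified RNA correlated at r = 0.068. Those of amplified and newly transcribed RNA correlated at r = 0.31. Probe sets are not independent replicates. The differences of total and newly transcribed RNA correlated at r = -0.022 across all probe sets. Of the 214 probe sets called higher in total RNA, 49.1% were also higher on the contralateral newly transcribed array, against 50.1% of all probe sets. Of the 45 called lower, 62.2% were also lower. Over the 3 preparations, 53 probe sets (48 genes) were called higher in each and 8 (8 genes) lower in each. If the newly transcribed calls were independent of the 93 and 15 shared ones, these numbers would be 23.5 and 4.32. The calls are not independent, since the tests share each probe set's spread and amplified and newly transcribed differences went together across all probe sets. The excess alone therefore does not show a response common to the 3 preparations. The genes higher in each include the steroid-induced cochaperone Fkbp5, the cytokine receptor gene Osmr, fibrinogen alpha (Fga), Klf4, Jun and Thbd.

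Newly transcribed RNA of contralateral kidneys was compared with that of normal kidneys, 1 array against 1. The genes with the largest higher signal on the contralateral array, among those named by the rule, were the acute phase genes Hp (5.21), Socs3 (4.30) and Cebpd (3.97), the interferon-induced genes Ifit1 (4.06) and Gbp2 (3.63), the lipid droplet gene Plin4 (3.82), the imprinted non-coding RNA Meg3 (3.61) and Apom (3.53). Those with the largest lower signal were the ERK phosphatase gene Dusp6 (-4.00), the NADPH oxidase gene Nox4 (-3.90), the chromatin remodelling gene Pbrm1 (-3.72), the purine synthesis gene Ppat (-3.61), Klhl42 (-3.57), Lin7c (-3.50), Slc4a4 (-3.46) and Nat2 (-3.42). Igfbp1 differed by 2.48, Cdkn1a by 3.12, Mt1 by 3.32 and Cyp27b1 by -1.92.

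Of the 13575 probe sets, 4458 differed by at least 2-fold between these arrays. The spread used for the test came from the other preparations, and the newly transcribed arrays have no replicate that could show their own. Only on the assumption that they vary alike did 3433 pass as higher and 3907 as lower, and the tallies of list members rest on it too. Ribosomal protein genes were higher in 36 of 46 and lower in 3 (39 and 3 adjusted over the list alone), with a median of 1.01 (adjusted p = 0.23 with an estimated correlation). Respiratory chain subunits were higher in 51 of 75 and lower in 9 (51 and 9 adjusted over the list alone), with a median of 0.82 (adjusted p = 0.211 with an estimated correlation). Both medians lay above all 10000 matched random lists, on the same arrays that differed in Gapdh 3'/5' ratio (68.9 against 12.7). So did those of acute phase genes (1.55) and NF-kB genes (1.63). The median of NRF2 and metallothionein genes (1.08) lay at percentile 99.97 and that of interferon-stimulated genes (0.78) at 99.54. Among lists that did not pass, immediate early regulators (median 0.83) lay at percentile 99.98 and tubular injury markers (0.98) at 99.73. Glucocorticoid-responsive genes (0.52) lay at percentile 97.79. Acute phase genes were higher in 15 of 19 (16 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation), NF-kB genes in 8 of 10 (8 adjusted over the list alone; adjusted p = 0.211 with an estimated correlation) and interferon-stimulated genes in 9 of 16 (9 adjusted over the list alone; adjusted p = 0.235 with an estimated correlation). NRF2 and metallothionein genes were higher in 10 of 15 and lower in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation).

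Markers of other cells differed on the same pair of arrays. Leukocyte markers were higher in 9 of 16 (9 adjusted over the list alone), with Fcer1g at 2.76 and C1qb at 1.56 (adjusted p = 0.489 with an estimated correlation). Of the adipose, muscle and adrenal markers 4 of 5 were higher (4 adjusted over the list alone), among them the adipocyte hormones Retn (2.65) and Adipoq (2.04) and the fatty acid binding protein Fabp4 (1.79); adjusted p = 0.29 with an estimated correlation. Glucocorticoid-responsive genes, with 11 of 22 higher and 5 lower (11 and 6 adjusted over the list alone; adjusted p = 0.057), and immediate early regulators, with 13 of 25 higher and 5 lower (14 and 5 adjusted over the list alone; adjusted p = 0.142), did not pass between these arrays. Other lists that did not pass include red blood cell genes (3 of 3 higher, 3 adjusted over the list alone; median 1.43, percentile 99.15 of matched random lists) and fibroblast and smooth muscle markers (7 of 12 higher and 1 lower, 7 and 1 adjusted over the list alone; median 0.85, percentile 99.44). Collecting duct markers (7 of 15 higher and 1 lower, 8 and 1 adjusted over the list alone; median 0.74, percentile 98.57) did not pass either. The circadian clock list, which also did not pass (adjusted p = 0.233), had a median of -0.82, at percentile 0.56 of matched random lists, with Nr1d2 at -2.17 and Clock at -1.87.

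The contralateral effect itself was then compared between preparations. Between newly transcribed and amplified total RNA it passed as different for 5687 probe sets, 2609 higher and 3078 lower in newly transcribed RNA, again only if the lone newly transcribed arrays vary like the others. The effect on Tmsb10 was 3.63 higher, on Ifit1 3.61 higher and on Hp 3.36 higher in newly transcribed RNA, and on Dusp6 it differed by -4.08. The difference was higher for ribosomal proteins (34 of 46 higher and 3 lower; 35 and 3 adjusted over the list alone; adjusted p = 0.219 with an estimated correlation) and respiratory chain subunits (46 of 75 higher and 8 lower; 48 and 8 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation). It was also higher for acute phase genes (10 of 19 higher and 1 lower; 11 and 1 adjusted over the list alone; adjusted p = 0.243 with an estimated correlation), interferon-stimulated genes (7 of 16 higher and 1 lower; 7 and 1 adjusted over the list alone; adjusted p = 0.251 with an estimated correlation) and NF-kB genes (5 of 10; 5 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation).

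Between amplified total and total RNA the contralateral effect differed for 606 probe sets, 87 higher and 519 lower in amplified RNA. The difference for Malat1 was -4.88 ± 0.27, for Slc4a4 -3.06, for the potassium channel gene Kcnj15 -2.93 and for the chromatin gene Atrx -2.92; for the postsynaptic protein gene Nrgn it was 2.01. Glucocorticoid-responsive genes had a median difference of -0.20, with Mt1 higher (1.21) and Klf9 (-0.94) and Glul (-0.55) lower among 22 (1 and 2 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation). Short-lived regulators also had a median of -0.20, with Arid5b (-1.50) and Foxo3 (-1.47) lower among 30 (4 lower adjusted over the list alone; adjusted p = 0.361 with an estimated correlation). The count of 606 was 311 and 273 without normal amplified replicate 1 or 2, 288 without normal total replicate 2 and 347 without contralateral total replicate 1.

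Newly transcribed RNA was next set against amplified total RNA of the same kidney groups, on the reading that both went through amplification. The titles name amplification for the amplified total RNA only. These preparations also differ in 3' bias (Gapdh ratios of 12.7 and 68.9 against 4.21 to 6.23). The sort of RNA and its quality therefore go together. Saa3, an acute phase gene, was higher by 3.40 ± 0.48 (adjusted p = 0.000919), the hexosamine pathway enzyme gene Gfpt2 by 2.36, the G protein gene Gna13 by 2.33, Ampd2 by 2.27, Sox6 by 2.25, the transcription factor gene Klf5 by 2.23, Dtx2 by 2.13 and the gap junction gene Gja1 by 2.11. Apoe, the apolipoprotein gene, was lower by -2.90 ± 0.44 (adjusted p = 0.00125), the mitochondrial ribosome gene Mrpl42 by -2.77, Ssr4 by -2.49, the proteasome gene Psmb7 by -2.47, the lysosomal channel gene Mcoln1 by -2.43, the deacetylase gene Sirt2 by -2.40, Acsm3 by -2.39 and Tmlhe by -2.35. The other probe set of Ssr4 and 2 of the 5 others of Gna13 went the other way.

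In all 1616 probe sets were higher and 2269 lower in newly transcribed RNA. Respiratory chain subunits were lower in 46 of 75 and higher in 0 (48 and 1 adjusted over the list alone), with a median of -0.85 and Ndufs4 at -2.17 (adjusted p = 0.387 with an estimated correlation). Ribosomal proteins were lower in 26 of 46 and higher in 3 (28 and 3 adjusted over the list alone; adjusted p = 0.549 with an estimated correlation). Proteasome subunits were lower in 20 of 37 and higher in 1 (21 and 1 adjusted over the list alone), and their call held with an estimated correlation (adjusted p = 0.0468). Endothelial markers were lower in 8 of 14 (9 adjusted over the list alone), with Tek at -1.54 and Emcn at -1.44 (adjusted p = 0.219 with an estimated correlation). Podocyte markers were lower in 5 of 7 (5 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation) and proximal tubule markers in 8 of 22 (11 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation), with the anion transporter Slc22a8 at -1.27.

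Other lists were higher in newly transcribed RNA. The list of transcription and chromatin regulators with short-lived mRNA was higher in 11 of 30 (12 adjusted over the list alone), with Klf5, Foxo1 (1.72) and Foxo3 (1.64) ahead (adjusted p = 0.211 with an estimated correlation). Clock genes were higher in 5 of 13 (6 adjusted over the list alone), with Rora at 1.49 and Hlf at 1.40 (adjusted p = 0.211 with an estimated correlation). Acute phase genes were higher in 7 of 19 and lower in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.496 with an estimated correlation) and NF-kB genes in 6 of 10 (8 adjusted over the list alone; adjusted p = 0.475 with an estimated correlation). The p53 targets were higher in 7 of 14 (8 adjusted over the list alone), with Trp53inp1 at 1.52 (adjusted p = 0.214 with an estimated correlation). Glucocorticoid-responsive genes were higher in 10 of 22 and lower in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.211 with an estimated correlation), with Zbtb16 at 1.94. With the Gapdh 3'/5' ratio as a covariate, a fit added after seeing the data, 1522 of the 3885 called probe sets were still called and Gfpt2, Dtx2 and Gja1 turned negative (-1.59, -0.81 and -0.36). With total RNA as the reference Gna13 turned to -0.13. With array weights in the additive model the count was 25. These weights do not measure the noise of the newly transcribed arrays, which have no replicate. The additive model also counts a contralateral effect that differs between preparations as spread. Of the 16 genes named first, Gfpt2, Sox6 and Dtx2 lost the call in at least 1 of the 10 fits that left out an array.

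Amplified total RNA was set against total RNA to see what the amplification named in its titles changes. Sdc4, a cell surface proteoglycan gene, was higher by 2.73 ± 0.28 (adjusted p = 0.000105), Pon2 by 2.28, the nuclear pore gene Nup107 by 2.27, Itsn1 by 2.25, Pyroxd1 by 2.20, Bnip2 by 2.14, Apob by 2.09 and Eif2s3y by 2.07. The calcium-binding protein gene S100g was lower by -3.66 ± 0.30 (adjusted p = 4.1e-05), Actb by -3.50, Ccnt1 by -3.09, Fmc1 by -2.92, the brush border peptidase gene Anpep by -2.86, Timm10b by -2.86, Ppp1r1a by -2.85 and Bicc1 by -2.77. The other probe set of Sdc4 went the other way. In all, 2816 probe sets were higher and 2393 lower. Respiratory chain subunits were lower in 31 of 75 and higher in 10 (32 and 10 adjusted over the list alone; adjusted p = 0.612 with an estimated correlation), ribosomal proteins lower in 18 of 46 and higher in 4 (18 and 4 adjusted over the list alone; adjusted p = 0.708 with an estimated correlation). Proximal tubule markers were lower in 8 of 22 and higher in 1, the glucose transporter Slc5a2 at 1.14 (9 and 1 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation). The Gapdh 3'/5' ratio went from at most 1.12 to at least 4.21 between these preparations. The count of 5209 was 7898 and 7921 without the normal or the contralateral newly transcribed array.

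**Figure D3:**
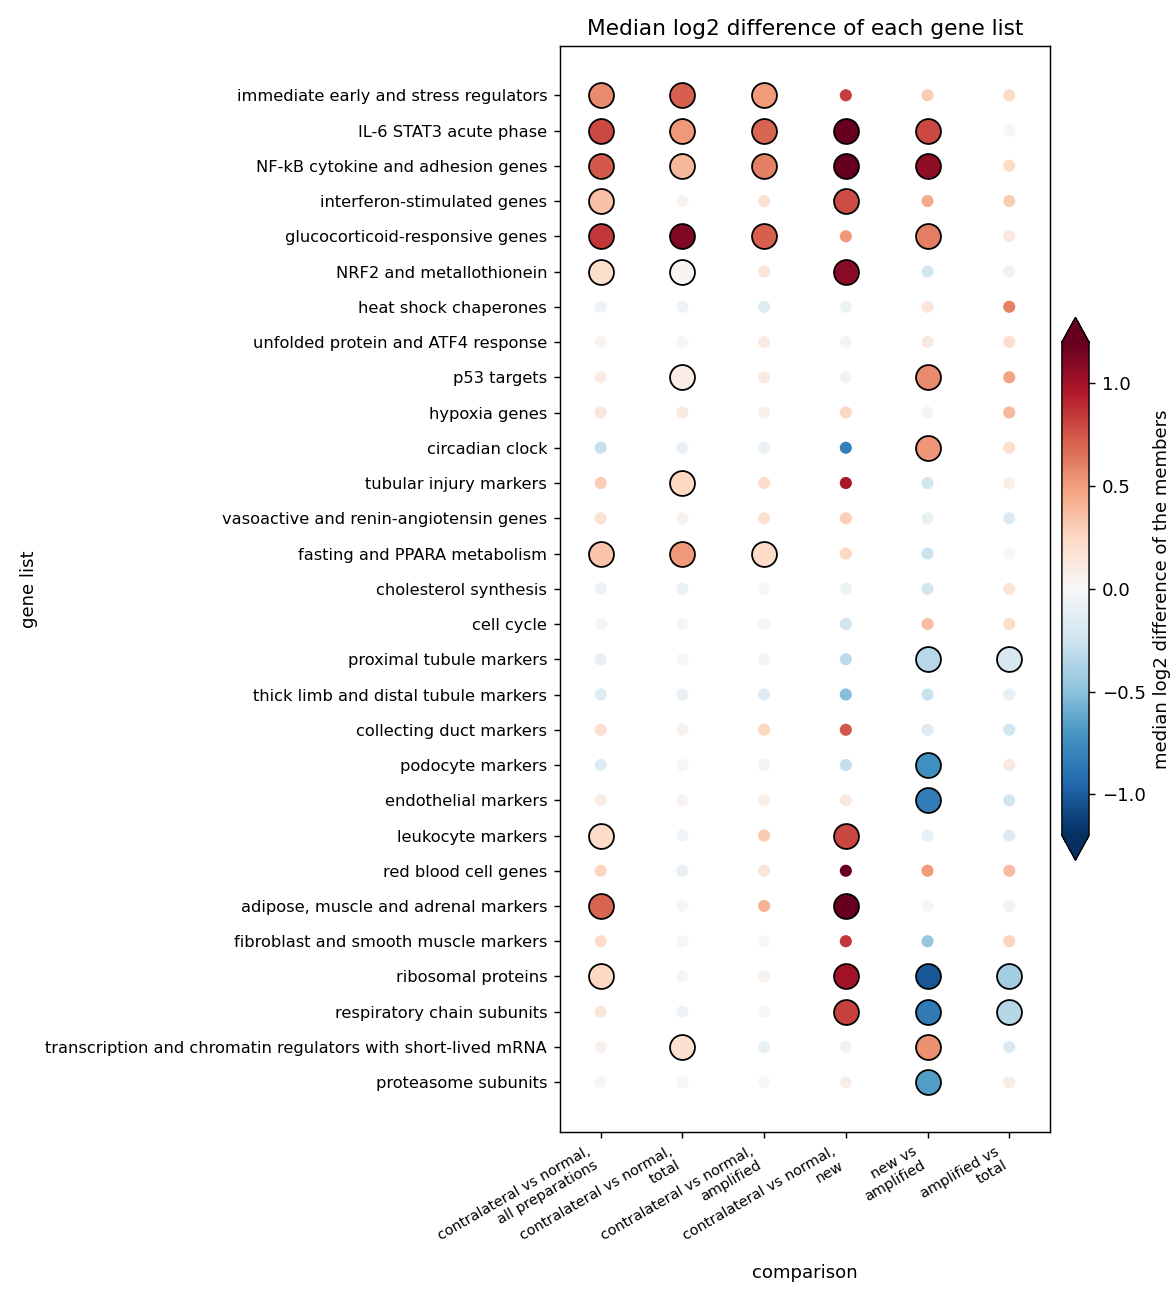
Median log2 difference of the members of each gene list (rows) in 6 comparisons (columns, as first minus second group); large outlined dots passed the set test at the preset correlation of 0.01, small dots did not, and the colour scale is in log2 units. Glucocorticoid-responsive genes passed in the contralateral comparisons of total and amplified total RNA, with medians of 1.12 and 0.72 (adjusted p = 0.0362 and adjusted p = 0.0782 with an estimated correlation). Respiratory chain subunits had medians of 0.82 between the newly transcribed arrays and -0.85 in newly transcribed against amplified total RNA (adjusted p = 0.211 and adjusted p = 0.387 with an estimated correlation).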

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

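The tests in this part were chosen before their results were seen, except the fit with the Gapdh covariate, which was added after the arrays' quality was seen, and the sizes of differences under other scalings, the leukocyte medians of the amplified and newly transcribed RNA, the splits balanced by preparation and the covariate's share in total RNA, which were added after the first results were seen. By the rules set beforehand, the share of 80.2% would have counted for poorer amplification. The share of 47.8% would have counted against a response like that of total RNA. Both readings were withdrawn after the results were seen. The count of 82 on the signals as deposited counted for the scaling between arrays by its rule, and the test of sizes was added after it.

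A ratio from control probe sets, outside the comparisons of genes, stood apart. The contralateral newly transcribed array had a Gapdh 3'/5' ratio of 68.9 and an Actb ratio of 24.8, where the normal newly transcribed array had 12.7 for each.

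The contralateral effect differed between newly transcribed and amplified total RNA, by a test of the difference that assumes the lone newly transcribed arrays to vary like the others, for 5687 probe sets. It was higher in newly transcribed RNA by 3.63 for Meg3, 3.63 for Tmsb10, 3.61 for Ifit1, 3.61 for Thap7, 3.57 for Tpm2, 3.39 for Apom, 3.39 for Ift27 and 3.36 for Hp. It differed by -4.08 for Dusp6, -3.86 for Nox4, -3.63 for Nat2, -3.63 for Lin7c, -3.44 for Ppat, -3.27 for Map4k5, -3.25 for Zfp207 and -3.25 for Spg21.

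The pattern behind this is that 7340 probe sets passed between the newly transcribed arrays, 1 against 1 and on the same assumption. If poorer, more 3'-biased amplification of the contralateral RNA were the whole cause in the form that amplification takes in normal kidneys, the difference would follow that of amplified against total RNA; across probe sets the correlation was -0.14 (95% bootstrap interval -0.16 to -0.12), which argues against it. Of the called probe sets, 47.8% (95% interval 46.7 to 48.9) moved the same way in total RNA. There 259 probe sets passed and the median absolute log2 difference was 0.159, so most directions in total RNA rest on small differences. This share therefore cannot decide whether a response like that of total RNA accounts for the pattern. The intervals in this part treat probe sets or genes as independent, which they are not. The ratio of 68.9 shows a stronger 3' bias on that array, so a loss of RNA of another form may still contribute, and no replicate array was there to tell. A change of synthesis in the contralateral kidney, which the design names, stays open and untested.

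The contralateral effect also differed between amplified total and total RNA, by a test of the difference, for 606 probe sets. It was higher in amplified RNA by 2.01 for Nrgn, 1.53 for Ubr3, 1.49 for Maz, 1.44 for Pqlc3, 1.37 for Rasl12, 1.35 for Ampd2, 1.34 for Rps27 and 1.29 for Appbp2os. It differed by -4.88 for Malat1, -3.06 for Slc4a4, -2.93 for Kcnj15, -2.92 for Atrx, -2.76 for Zbtb20, -2.73 for Slc6a6, -2.44 for Clcn3 and -2.42 for Reep3. Of the genes with a higher effect, Nrgn, Ubr3, Maz, Pqlc3, Rasl12, Rps27 and Appbp2os lost the call in at least 1 of the 8 fits that left out an array. Over the alternative fits, Rps27 kept its call in 2 of 16 and Maz in 6 of 16. Rasl12 and Appbp2os kept theirs in 8 of 16 each, Pqlc3 in 10 of 16 and Nrgn in 14 of 16.

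Both preparations start from total RNA, so a kidney response alone would not be seen to differ between them. Of the 606 probe sets, 80.2% (95% interval 77.0 to 83.4) moved the same way between the newly transcribed arrays, which share no array with this test. Poorer amplification of the contralateral RNA would give such a share, and so would a change present in both amplified total and newly transcribed RNA. These cannot be told apart, since the difference between the newly transcribed arrays did not itself follow the effect of amplification. The count was 82 on the signals as deposited, which by the rule set beforehand counted for the scaling between arrays as the cause. The sizes of the differences were compared afterwards, for the probe sets called after quantile normalization. Their median ratio to the sizes after that normalization was 0.823 (95% bootstrap interval 0.813 to 0.832) on the signals as deposited. There the median shift of 0.30 was not removed, and the median standard error was 0.521 instead of 0.225. With the arrays scaled to one median the ratio was 1.01, and 548 of the 606 were still called. For these probe sets most of the size was thus kept under the other scalings, while the number called depended on the scaling. RNA from different mice in the preparations was not excluded, since the labels do not tie them.

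The 60 probe sets that passed over all preparations could come from the same differences in RNA quality. With the Gapdh 3'/5' ratio as a covariate the median ratio of their log2 changes to those without it was 0.911 (95% bootstrap interval 0.873 to 0.951), and 60 of 60 were still called, which argues against the 3' bias of the newly transcribed arrays, where 92.5% of the covariate's variation within preparations lies. Of that variation 1.21% comes from the total RNA arrays, whose ratios parted by kidney group, so 3' bias and kidney cannot be told apart in total RNA. For total RNA, leukocytes in the contralateral kidney are argued against by a median of -0.042 (95% bootstrap interval -0.18 to 0.078) over 16 leukocyte markers; the median was 0.32 (0.11 to 0.38) in amplified total and 0.80 (0.45 to 1.10) in newly transcribed RNA, so a contribution there stays open. Surgery, anaesthesia and the later time point go with the kidney group and stay open, as does a response of the kidney itself.

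For the 60 probe sets chance is not excluded by the count of splits. Among the 36 splits with equal numbers of each preparation on both sides, 2 called at least as many, the real one included. The highest other count, 71, came from exchanging the kidneys of total RNA alone; it still keeps the kidney groups apart within each preparation, so it points to a contralateral effect that differs between preparations, and the other 34 called 0. Of 100 splits drawn without that balance 4 called as many. The highest, 5950, came from splits in which, with preparation in the model, only the newly transcribed arrays differ, and it points to their difference.

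For amplified total against total RNA, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, called as many as 5209. The highest of the others was 923. A share of 1 in 35 is the smallest this test can give, so chance is made less likely but not excluded. The test also takes the arrays as independent, while total and amplified arrays may come from the same mice.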

How the results depend on the processing

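The labels share replicate numbers between groups, but nothing ties the numbers to a mouse. The deviations of arrays of one number correlated at -0.07 to 0.10 between groups. Total and amplified total RNA of one kidney group gave the highest values, 0.10 (contralateral) and 0.097 (normal). Pairs across kidney groups gave -0.07 to 0.042. Such weak correlations cannot show whether arrays of one number share a mouse. With the replicate block the count over all preparations was 26 instead of 60, and it moved no other count by over 1.5 times (277, 1429, 7403, 2648, 4686, 5763 and 620). Among the alternative counts 50 moved by over 1.5 times and 117 did not, and the causes were not tested unless the setting itself shows it. Fits without a newly transcribed array, the Gapdh covariate and lists on median-scaled arrays were chosen after seeing the data.

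On the signals as deposited, the median probe set shifted by -0.56, -0.43, -0.13 and -1.64 in the contralateral comparisons (all preparations, total, amplified, newly transcribed) and by -0.14 in newly transcribed against amplified, -0.07 in amplified against total RNA, and -1.50 and 0.30 in the differences of the effect. List medians were taken relative to this shift, where it exceeded 0.1, and 0 called lists then turned. This was decided after the unadjusted medians of many list results were seen to change sign. The counts were 11 (5 higher, 6 lower, against 52 and 8), 38 (15 and 23, against 214 and 45), 352 (23 and 329, against 556 and 844), 9991 (68 and 9923, against 3433 and 3907), 455 (59 and 396, against 1616 and 2269), 1371 (370 and 1001, against 2816 and 2393), 7581 (42 and 7539, against 2609 and 3078) and 82 (6 and 76, against 87 and 519). Scaled to one median, the probe sets of amplified against total RNA shifted by 0.20 and split into 4092 higher and 1752 lower.

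The contralateral count over all preparations was 416 with array weights, 145 with the Gapdh covariate, 321 on total and amplified arrays only, 1052 with the number within a kidney group as a random block (consensus correlation -0.23), 611 on means per number and 154 at an adjusted p under 0.10. In total RNA it was 87 without a filter, which tests more probe sets, 145 without the intensity trend and 449 at 0.10; in amplified RNA 2110 at 0.10, and for the difference between amplified and total RNA 939 at 0.10. Newly transcribed against amplified RNA gave 25 with array weights, 2300 without the total RNA arrays, 6806 with total RNA as the reference and 7514 with 6 group means. Amplified against total RNA gave 8190 with array weights and 7908 on its own arrays only. With an estimated correlation 4 of 54 list calls remained. Leaving out single arrays gave 12 to 332 over all preparations, 48 to 376 in total, 513 to 1293 in amplified and 6957 to 7639 in newly transcribed RNA, 2801 to 6733 and 4025 to 7921 between preparations, and 4610 to 5749 and 273 to 696 for the differences.

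In newly transcribed against amplified RNA 18 named genes turned. With total RNA as the reference these were Gna13 (-0.13), Cdkn1c (0.067), Creld2 (0.71), Hbegf (-0.096), Cyp51 (0.18) and Ptprc (0.18). With the Gapdh covariate they were Gfpt2 (-1.59), Dtx2 (-0.81), Gja1 (-0.36), Socs3 (-1.02), Irf1 (-0.49), Tap1 (-1.27), Hspb8 (-0.94), Hk2 (-1.13), Slc2a1 (-1.07), Pfkfb3 (-0.13), Dpp4 (0.033) and Pecam1 (0.40). No other named gene turned in the alternatives run; over these, 4507 gene results kept their side of the threshold, 860 lost the call and 18 gained it. Without detection calls, the limit that dim signals set is unknown.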

Other observations

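The tests in this part were chosen before their results were seen. The comparison with the genes that fell was added afterwards.

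Some genes outside the lists that passed over all preparations were called higher in contralateral kidneys in each of the 3 preparations. They were chosen after their values were seen and were not tested as a set. Psat1, Sesn2 and Thbd were already named above. Psat1, an enzyme of serine synthesis, was higher by 1.33 in total, 0.97 in amplified and 1.77 in newly transcribed RNA, and Sesn2 by 1.88, 1.02 and 1.83. Upp2, a uridine phosphorylase gene, was higher by 1.62, 1.42 and 1.48, and Arg2, the mitochondrial arginase gene, by 0.90, 1.25 and 1.22. Among vascular and matrix genes, the gene of the thrombin-binding protein thrombomodulin (Thbd) was higher by 0.98, 0.58 and 1.11, and the collagen crosslinking enzyme gene Lox by 0.96, 0.89 and 1.71. Psat1 and Sesn2 belong to the unfolded protein and ATF4 response list, which did not pass over all preparations (adjusted p = 0.722, 2 of 19 members called).

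One hypothesis was that messages that turn over fast, or are strongly transcribed, respond first, so that genes higher in contralateral total RNA take a large share of new RNA in normal kidneys. The 117 genes concerned had a median newly transcribed minus amplified total difference of 0.47 in normal kidneys, at percentile 100 of 10000 random lists matched on mean signal, whose medians lay between -0.20 and 0.12 in 95% of draws. The 32 genes that were lower in total RNA had a median of 0.42, so the share of new RNA may go with change in either direction rather than with a rise. The normal newly transcribed RNA is 1 array, and its Gapdh 3'/5' ratio of 12.7 was above those of amplified total RNA, so the sort of RNA and its quality go together here.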
